A study of Mus musculus with 2 samples.

How the data were processed

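H3K27ac, the acetylation of lysine 27 of histone H3 that marks active promoters and enhancers, was measured by chromatin immunoprecipitation and sequencing in the neural tube of mouse embryos at embryonic day 11.5. Per the labels, the embryos were of strain B6NCrl and of both sexes, and tissue from many embryos was pooled for each of 2 biological replicates: 109 embryos for replicate 1 and 88 for replicate 2. Both replicates form 1 group, so no comparison between groups was possible.

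The starting point was 4 deposited peak lists in narrowPeak format on the mouse assembly mm10. Per the text files deposited with them, the list of each replicate was made from that replicate's filtered alignments and control alignments, the pooled list from the alignments of both replicates, and the replicated list from the other 3 lists. The peak caller, its version, its threshold and the rule for the replicated list are not given in the sources used here. The signal value of a peak is the value that the authors' peak caller gave it, described here in its own unit. It had been taken for fold enrichment over control before the data were examined, and since no header states this, it is called signal value. It was used to describe, rank and filter peaks, averaged over both replicate lists to rank genes and compare promoters, correlated between these lists by rank, and compared between promoters by permutation tests. The authors also deposited a -log10 p and a -log10 q for each peak and the position of its summit. The files hold no read counts, so the sequencing depth of each replicate is unknown, and no interval that depends on it is given. All 95% intervals are Wilson binomial intervals on counts of peaks or genes, or exact Poisson intervals on peak densities; they cover counting error only.

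Peaks on the 19 autosomes, X and Y were used. Peaks on unplaced scaffolds were left out of every comparison, 8 in the list of replicate 1, 4 in that of replicate 2, 5 in the pooled list and 4 in the replicated list. Gene models were those of GENCODE vM21 on the GRCm38.p6 genome, the same build as mm10, with 21938 protein-coding genes on these 21 chromosomes. The transcription start site (TSS) of a gene was its annotated 5′ end, and its promoter was the TSS with 1 kb on each side. The signal value of a promoter was the highest among the peaks overlapping it, whose summits can lie outside the promoter. A peak was called distal when it lay more than 2 kb from each of the 132629 annotated transcript starts.

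A peak was counted as shared when the other replicate's peaks covered at least 50% of its length. The observed share was set against 1000 circular shifts of the other list within each chromosome, with assembly gaps removed, in a one-sided permutation test. Each list was also divided into 10 equal classes by its own signal value, and Spearman's rho was computed across matched peaks, which are not independent replicates. The centre of each replicated peak was placed at a promoter, else in an exon, else in an intron, else between genes, and tested against 1000 shifts in a two-sided permutation test. Permuting positions describes these libraries and says nothing of other embryos.

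Before the data were examined, 19 gene lists were fixed with 383 entries and 376 different genes; 1 symbol, Tf, was matched through its synonym to Trf, and 0 were unmatched. For each list, members with a replicated peak overlapping the promoter were compared with all other protein-coding genes by Fisher's exact test, two-sided. The mean number of distal replicated peaks within 50 kb of the TSS was compared with 100000 random lists of as many other genes in a two-sided permutation test. Genes with a promoter peak in 1 replicate only were compared between the replicates by an exact binomial test, two-sided, which turned out to have too few such genes to pass in any list. Each of these families of tests was adjusted by the Benjamini-Hochberg method over the 19 lists, with 0.05 as the threshold. The lists for other brain regions, crest, glia, mesoderm, blood, vessels, endoderm, ectoderm and germ line stand for cells that the dissected tissue could hold. The genes named in the text were fixed by rule. Among the members of each list with a replicated promoter peak, up to 4 with the highest mean signal value over both replicates were taken. In lists with fewer than 50% such members, the first 4 without one in the list's order were also taken. Added to these were the genes of the 25 domains with the most bases in replicated peaks. The 10 genes with the highest pooled promoter signal value and all Hox genes completed the set. Members named beyond this rule were chosen after their values were seen.

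Replicated peaks within 12500 bp of each other were stitched into domains, ranked by the base pairs that peaks cover. Hox paralogs 1 to 9 were compared with paralogs 10 to 13 by Fisher's exact test, two-sided, with each gene counted once even where neighbours share a peak. For 20 textbook consensus motifs, the 500 bp round the summits of distal replicated peaks were compared with as many windows outside all peaks and more than 2 kb from transcript starts on the same chromosome, each matched on GC content as the closest of 200 random positions, by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 20 motifs. Peak densities of X, Y and autosomes were computed per Mb of sequenced bases.

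The alternatives covered the overlap that counts as shared, stricter peak thresholds, the peak list used, the promoter and distal windows, the transcript starts, the background genes or windows, the stitching distance and the use of 1 replicate's own list in place of the replicated one. No samples were paired across groups, so there was no block to fit. The methods were tested on simulated data. With 20.0%, 40.0% and 79.9% of peaks copied, the overlap test returned 20.7%, 40.3% and 79.9%. Of the simulated lists with a changed promoter share, 99.5% were called in the right direction among the 21938 genes, and 0.917% of unchanged lists were called. The changes added there were large, near the strongest of the real lists, and smaller changes of the promoter share were not simulated. A list with distal peaks raised 2, 4 or 7 times was called in 5.0%, 75.0% and 95.0% of simulations over the same genes. Each factor was given to a different list, of 18, 25 and 15 genes in this order, so factor and list size vary together. Counts were drawn independently for each gene, while real neighbours can share distal peaks. A motif added to 3000 windows with an excess of 4.57% was recovered with an excess of 4.37%. The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pysam 0.24.0 and matplotlib 3.10.9, and samtools 1.23.1.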

Results

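Peaks of H3K27ac, a mark of active promoters and enhancers, were listed for the neural tube of mouse embryos at embryonic day 11.5. The design held 1 group with 2 biological replicates, pools of 109 and 88 embryos. On the autosomes, X and Y the list of replicate 1 held 62257 peaks covering 27.7 Mb, and that of replicate 2 held 62151 peaks covering 26.8 Mb. The pooled list held 45994 peaks covering 26.5 Mb, and the replicated list 30664 peaks covering 22.6 Mb. Median peak widths were 273, 270, 356 and 507 bp in the same order. Signal values are those of the authors' peak caller, in a unit that the sources do not state, and how well they compare from list to list is not known. The depth of the libraries is unknown, and with 1 group each result describes this tissue as dissected.

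The first comparison asked how far both replicates marked the same places. Nearly all peaks in the strongest of 10 classes of each list were found in both. The Hox clusters, the promoters of the neural progenitor regulators Nr2f1, Pou3f2 and Msi1, and those of the chromatin gene Setd1b and the RNA-binding protein gene Pcbp1 carried peaks in each list. The promoter of Setd1b had the highest signal value of all promoters in the pooled list, 58.5, and reached 44.5 in the list of replicate 1 and 50.8 in that of replicate 2. Next came Arrdc3 with a pooled signal value of 56.9, Pcbp1 with 51.4, Zc3h4 with 49.6, and Zc3h6 and Gm10762 at a single peak with 49.1. Arid2 had 47.3, Nfyb 47.1 and Zfp827 46.6. Hoxb7 came last with 45.3, tied with Hoxb3, Hoxb4, Hoxb5, Hoxb6, Hoxb8 and Hoxb9, which lie at the same single peak. The Arrdc3 promoter, which belongs to an arrestin-family gene, had a signal value of 53.3 in replicate 1 and of 16.1 in replicate 2.

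Of the peaks of replicate 1, 24921 (40.03%, 95% interval 39.6 to 40.4) were shared with replicate 2, against 1.08% for shifted positions. Of the peaks of replicate 2, 25913 (41.7%, 95% interval 41.3 to 42.1) were shared with replicate 1, against 1.13% for shifted positions. Both shares gave a one-sided permutation p of 0.001, the smallest that 1000 shifts can give. The lists shared 15.7 Mb, which is 40.3% of the bases that either covered. Sharing was much higher among strong peaks. In the weakest of 10 equal classes of each list by signal value 13.96% of the peaks of replicate 1 and 15.9% of those of replicate 2 were shared, and in the strongest class 98.5% and 99.2%. From class 6 upwards the share rose at each step, from 30.1% and 33.0%, to 84.2% and 87.0% in class 9, while in the 5 weaker classes it went up and down between 13.96% and 25.3%. Across the 24921 matched peaks, which are not independent, Spearman's rho of the signal values was 0.698. Peaks of replicate 1 with a -log10 q of at least 5 were found in the whole list of replicate 2 in 87.5% of cases, and 91.5% in the other direction, and with this limit on both lists the shares were 67.95% and 76.0%.

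**Figure D1:**
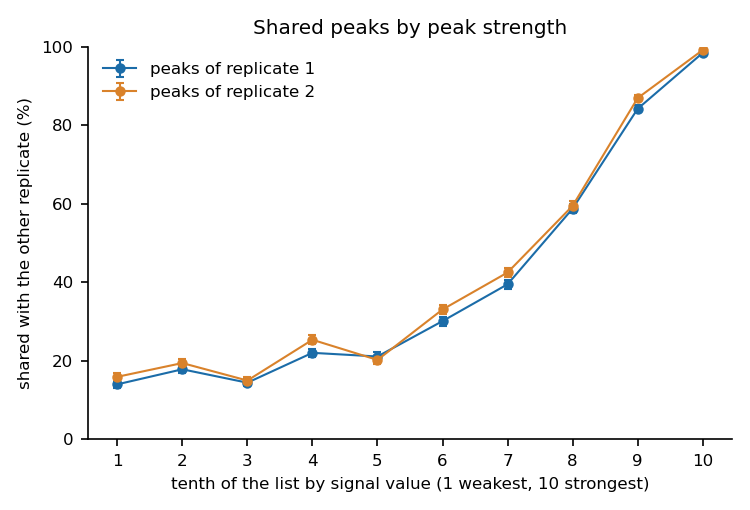
Share of each replicate's peaks (percent, vertical axis) that were shared with the other replicate, by class of the list's own signal value (horizontal axis, 10 equal classes, 1 weakest and 10 strongest), with 95% Wilson intervals as bars. From the first class to the last the share goes from 13.96% to 98.5% in replicate 1 and from 15.9% to 99.2% in replicate 2.

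The replicated list kept 30664 of the 45994 pooled peaks, or 66.7%. Kept peaks were wider, with a median of 507 bp against 229 bp for the others, and stronger, with a median pooled signal value of 4.47 against 3.05. Of the kept peaks 85.6% overlapped a peak of both replicates by at least 50% of either peak, and of the other 15330 pooled peaks 0 did so. The share kept was 98.8% among the 17489 pooled peaks with a -log10 q of at least 5.

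Replicated peaks were concentrated at the promoters of protein-coding genes. Centres within 1 kb of a TSS made up 31.5% of the peaks, 18.5 times the share of 1.71% at shifted positions, and exons held 5.98%, 1.67 times their chance share. In the lists of the single replicates promoters held less, 19.7% in replicate 1 and 19.6% in replicate 2, which is 11.6 and 11.5 times their chance share. Regions between genes held 26.4%, against 57.5% by chance. Each of these shares gave a two-sided permutation p of 0.002, the smallest that the shifts can give. Introns held 36.1% against 37.2% by chance (permutation p = 0.184), and 42.9% to 43.2% of the peaks in the lists of the single replicates, above chance in both with the smallest permutation p of 0.002. In the pooled list they held 40.4%, above the 37.3% by chance (permutation p = 0.0040). The intron share was below chance with only peaks of -log10 q of at least 5 (28.2% against 37.2%, permutation p = 0.002), with promoters of 2.5 kb on each side (33.8% against 36.1%, permutation p = 0.00999) and with every annotated transcript start counted as a promoter (30.9% against 35.6%, permutation p = 0.002), so its direction depends on these choices. With every transcript start the exon share was 2.75%, and its difference from chance was not past the threshold (permutation p = 0.360). In all, 9253 of the 21938 protein-coding genes (42.2%) had a replicated peak at their promoter. Of the replicated peaks, 15087 (49.2%) were distal, a mean of 0.647 per gene within 50 kb.

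The next comparison asked which programmes of the embryo carried the mark at their promoters. Neural progenitor genes, pan-neuronal genes, Hox genes of paralogs 1 to 9 and housekeeping genes were nearly all marked. Of the 25 neural progenitor genes 23 had a replicated promoter peak (92.0%, 95% interval 75.03 to 97.78, against 42.1% of other genes, adjusted exact p = 2.38e-06), and the same 23 had one in each replicate. By the mean over both replicates the first was Nr2f1, a nuclear receptor of neural patterning, with a signal value of 31.4 in replicate 1 and 28.5 in replicate 2, while Msi1 was higher in replicate 1 and in the pooled list (42.2 against 33.6). Pou3f2, a POU factor of neural precursors, had 28.8 and 27.6, the RNA-binding protein gene Msi1 36.1 and 13.1, and Cdh2, which encodes N-cadherin, 20.3 and 25.7. Pax6 and Hes3, looked up after the values were seen, were the members without a peak at their annotated 5′ end. With every annotated transcript start counted, 24 of the 25 genes were marked. Of the 25 pan-neuronal genes 23 were marked (92.0%, adjusted exact p = 2.38e-06), all 23 in each replicate, led in the mean over both by the helix-loop-helix gene Nhlh2 with signal values of 15.5 and 21.5, the neuronal tubulin gene Tubb3 with 17.2 and 10.5, the neurofilament gene Nefl with 11.1 and 9.73, and the zinc finger gene Myt1 with 11.3 and 9.5.

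Transcription factors of neurogenesis and of neuron classes were marked in 27 of 40 cases (67.5%, 95% interval 52.0 to 79.9, adjusted exact p = 0.00364), 31 in replicate 1 and 30 in replicate 2. Ebf3 led with signal values of 14.4 and 12.3, followed by Bhlhe22 with 7.67 and 10.8, Lbx1, a factor of dorsal interneurons, with 8.18 and 9.21, and the sensory neuron factor Pou4f1 with 7.92 and 9.01. This call ended when the background genes were matched on promoter GC content, where 58.4% were marked (adjusted exact p = 0.248), and with only peaks of -log10 q of at least 5 (20 of 40 genes, adjusted exact p = 0.0951). Housekeeping genes were marked in 22 of 25 cases (88.0%, adjusted exact p = 1.83e-05), with Actb at 27.99 and 23.7, Hmbs at 18.3 and 21.8, Vcp at 17.4 and 18.3 and Tubb5 at 13.4 and 16.3.

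Genes that set up the dorsoventral axis of the neural tube were marked about as often as other genes, 13 of 30 (43.3%, adjusted exact p = 1.0). The marked ones included Irx3 with signal values of 17.3 and 15.9, the dorsal factor Pax3 with 14.1 and 17.7, Irx5 with 16.4 and 12.3, and Gli2, a transcription factor of hedgehog signalling, with 10.5 and 12.3. Shh, the ventral signal of the floor plate, and the ventral factors Foxa2, Nkx2-2 and Nkx2-9 had no replicated promoter peak; Foxa2 had a peak with a signal value of 3.503 in replicate 1 only. Against background genes of the same promoter GC content, of which 64.1% were marked, the list was lower (adjusted exact p = 0.0197).

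Programmes of other regions and tissues were mostly unmarked. None of the 22 forebrain genes had a replicated promoter peak, among them Foxg1, Emx1, Emx2 and Six3 (0%, 95% interval up to 14.9%, adjusted exact p = 3.19e-05); Emx2 had a peak with a signal value of 4.43 in replicate 1 only. None of the 15 heart genes, such as Nkx2-5, Gata4, Gata6 and Tbx5, and none of the 15 surface ectoderm genes, such as the keratins Krt5, Krt8, Krt14 and Krt18, had one either (adjusted exact p = 0.000869 for each list). Of the 20 blood genes 1 was marked (adjusted exact p = 0.000892), Tal1 with 4.15 and 3.37, a gene that the neurogenic and endothelial lists also hold; Gata1, Klf1, Nfe2 and Hba-a1 were not. Of the 20 liver and endoderm genes 2 were marked (adjusted exact p = 0.00462), Trf with 3.89 and 4.14 and Foxa3 with a value in replicate 2 only, 3.24, while Alb, Afp, Apoa1 and Apoa2 were not. Pluripotency and germ line genes were lower too with 1 of 15, Dazl with 2.97 and 4.45 (adjusted exact p = 0.0103), and Pou5f1, Nanog, Zfp42 and Dppa3 were unmarked. Genes of mature glia were marked in 2 of 15 cases, Gja1 with 5.04 and 4.80 and Mbp with 3.44 and 3.39 (adjusted exact p = 0.0483), and Mog, Mag, Mobp and Cnp were not. The calls for blood and mature glia were not stable. In the list of replicate 2 alone 30.0% of the blood genes were marked (adjusted exact p = 0.284) and 33.3% of the mature glia genes (adjusted exact p = 0.556), in that of replicate 1 4 of 20 blood genes (adjusted exact p = 0.0364) and 3 of 15 mature glia genes (adjusted exact p = 0.0968), and against GC-matched genes the adjusted exact p was 0.0658 for blood and 0.0873 for mature glia. The mature glia call also ended in the pooled list (adjusted exact p = 0.264), with promoters of 500 bp or 2.5 kb on each side (adjusted exact p = 0.0501 and 0.105) and with every transcript start (adjusted exact p = 0.0972).

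Lists for neural crest, somites, vessels and midbrain did not pass the test. Neural crest and glia precursor genes were marked in 9 of 20 cases (adjusted exact p = 0.921), with the endothelin receptor gene Ednrb at 13.2 and 9.58, Twist1 at 10.8 and 8.83, Fabp7, which the progenitor list also holds, at 11.5 and 7.66, and Sox9 at 8.07 and 10.3; Sox8, Tfap2a, Ets1 and Foxs1 were not marked. Somite, muscle and skeletal genes were marked in 9 of 25 cases (adjusted exact p = 0.869), with Foxc1 at 11.7 and 15.4, the cartilage collagen gene Col2a1 at 13.2 and 11.9, Pdgfra at 9.16 and 8.83 and Foxc2 at 6.84 and 5.94; Mesp2, Pax1 and Pax9 were not, and Meox1 had a peak in each replicate (3.503 and 3.28) but none in the replicated list. Endothelial genes were marked in 7 of 18 cases (adjusted exact p = 0.921), with Fli1 at 6.62 and 5.40, Tal1 as above, Egfl7 at 3.503 and 3.84 and Cldn5 at 3.11 and 3.84; Pecam1, Kdr, Tek and Tie1 were not. With only peaks of -log10 q of at least 5, endothelial genes were lower (5.56%, adjusted exact p = 0.00961). Midbrain and isthmus genes were marked in 3 of 14 cases (adjusted exact p = 0.237), Gbx2 at 7.50 and 7.36, Nr4a2 at 5.63 and 4.88 and Tfap2b at 2.97 and 3.07, while Otx2, En2, Fgf8 and Fgf17 were not; against GC-matched genes the list was lower (adjusted exact p = 0.00553). Of the genes named here and above as unmarked, Sox8 (3.503), En2 (3.11) and Apoa1 (3.11) had a promoter peak in replicate 1 only, and Klf1 (3.07), Kdr (3.05) and Cnp (2.42) in replicate 2 only.

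**Figure D2:**
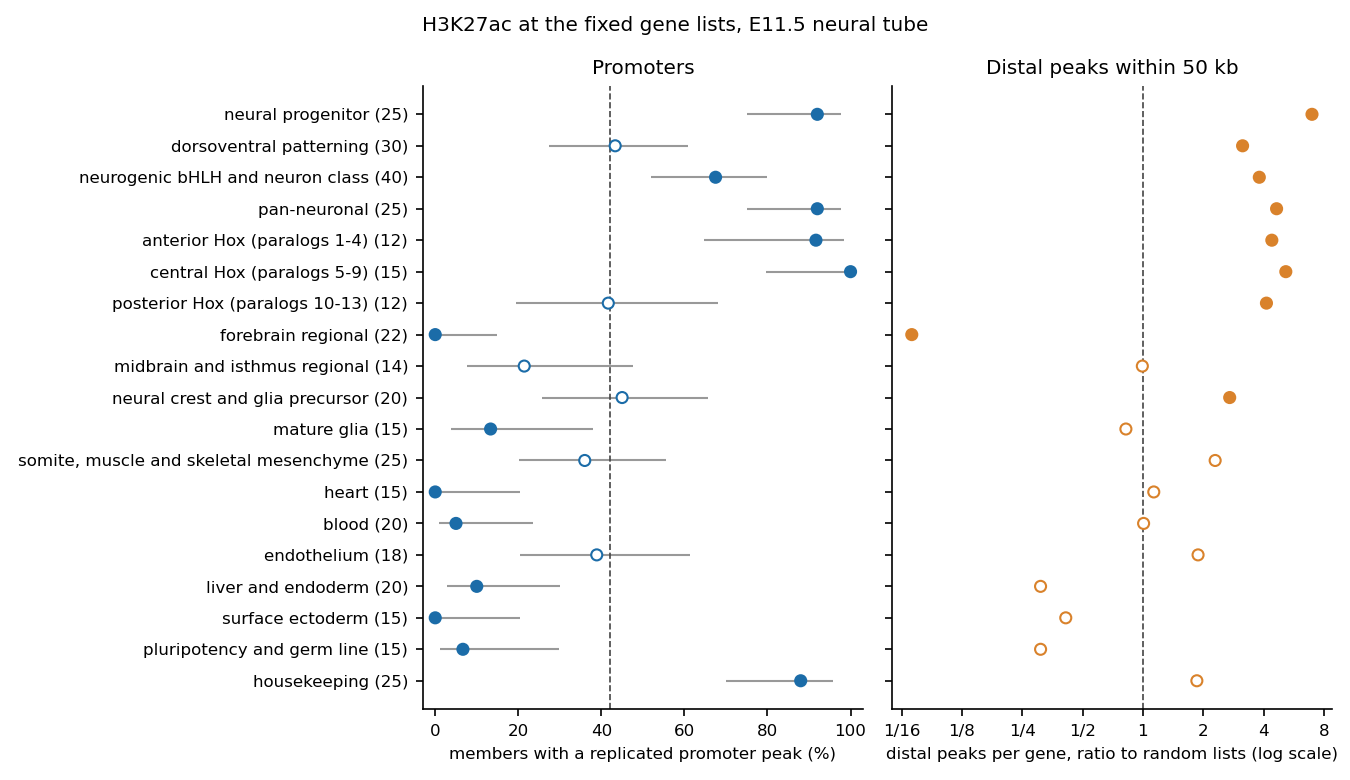
Left, percent of each gene list's members with a replicated promoter peak, with 95% Wilson intervals as bars and the share of all protein-coding genes, 42.2%, as a dashed line. Right, mean number of distal replicated peaks within 50 kb as a ratio to random lists on a log scale; filled points had an adjusted p under 0.05 and numbers in parentheses are the members of each list. The neural progenitor list stands at 92.0% and 6.98, the forebrain list at 0% and 0.0702.

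Distal peaks, where enhancers lie, were gathered round the same neural programmes. Neural progenitor genes had a mean of 4.48 ± 4.69 (SD over 25 genes) distal replicated peaks within 50 kb, 6.98 times the mean of random lists (adjusted permutation p = 0.000127). Of these, 12 lay round Msi1, 9 round Pou3f2, 4 round Nr2f1 and 0 round Cdh2. The ratio was 4.56 from the list of replicate 2 alone and 4.88 from that of replicate 1, 10.9 within 20 kb and 4.18 within 100 kb. Pan-neuronal genes had 4.65 times as many as random lists (adjusted permutation p = 0.000127), with 10 round Nhlh2 and 6 round Nefl. Neurogenic factors had 3.81 times as many (adjusted permutation p = 0.000127), with 8 round Ebf3. The genes named here lie above the medians of their lists, 2 for pan-neuronal genes and 1 for neurogenic factors. For these lists the unadjusted permutation p of 2e-05 is the smallest that 100000 random lists can give. Dorsoventral genes, not called at their promoters, had 3.14 times as many (adjusted permutation p = 0.00418) and a ratio of 5.73 within 20 kb. They had 10 round Pax3, 4 each round Irx5 and Gli2 and 2 round Irx3, with a median of 1 in the list. Neural crest genes had 2.71 times as many (adjusted permutation p = 0.0351), with 5 round Sox9 and a median of 0.5 in the list. Central, anterior and posterior Hox genes had 5.17, 4.40 and 4.14 times as many (adjusted permutation p = 0.000475, 0.00741 and 0.0105), counted on peaks that neighbouring Hox genes share. Forebrain genes had 1 distal peak in all, a ratio of 0.0702 (adjusted permutation p = 0.0209). The remaining 10 lists were not called, with ratios from 0.309 for liver and endoderm to 2.29 for somite, muscle and skeletal genes. From the list of replicate 2 alone, the ratios were 0.425 for forebrain (adjusted permutation p = 0.0981) and 2.05 for neural crest (adjusted permutation p = 0.0504); from that of replicate 1 the forebrain ratio was 0.296 (adjusted permutation p = 0.0251) and the somite list was called with 1.97 (adjusted permutation p = 0.0365). With only peaks of -log10 q of at least 5, the anterior and posterior Hox, forebrain and neural crest calls ended, with an adjusted permutation p of 0.0951 for forebrain and 0.0865 for the others. The forebrain call also ended within 20 kb (adjusted permutation p = 0.382), within 100 kb (adjusted permutation p = 0.257) and against random lists matched on promoter peaks (adjusted permutation p = 0.119), so it held in 3 of 8 alternatives. Neural crest was not called within 20 kb (adjusted permutation p = 0.0658). Somite genes were called within 20 kb (3.95 times, adjusted permutation p = 0.0116) and against the matched lists (2.42 times, adjusted permutation p = 0.0465), and endothelial genes within 100 kb (2.34 times, adjusted permutation p = 0.0448).

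The same lists were also counted in each replicate, and too few of their genes differed to say whether the 2 dissections were alike. No list had more than 9 genes marked in 1 replicate only. An exact binomial test could therefore not pass in any of the 19 lists, since the smallest adjusted exact p it could give was 0.0742. Genes marked in replicate 1 only and in replicate 2 only numbered 4 and 5 for dorsoventral genes, 5 and 2 for somite, muscle and skeletal genes, 3 and 2 for neurogenic factors, 1 and 3 for mature glia and for blood, 2 and 2 for liver and endoderm, 0 and 2 for posterior Hox genes and 2 and 0 for neural crest genes, and at most 1 of each kind in the other lists. Over all protein-coding genes 9152 had a promoter peak in both replicates, 1010 in replicate 1 only and 1024 in replicate 2 only.

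Hox genes, which give cells their position along the head-to-tail axis, were compared along each cluster. Of the 27 genes of paralogs 1 to 9, 26 had a replicated promoter peak, and of the 12 genes of paralogs 10 to 13, 5 did, a difference of 54.6 percentage points (Fisher's exact p = 0.000356). Neighbouring Hox genes often shared a peak: the 26 genes were marked by 16 different peaks and the 5 by 5, and 1 peak marked both Hoxc5 and Hoxc10. The tests of Hox genes count genes as independent and do not allow for this, so their p-values can be too small. All 15 genes of paralogs 5 to 9 were marked (adjusted exact p = 1.496e-05) and 11 of 12 genes of paralogs 1 to 4 (adjusted exact p = 0.00116); the exception was Hoxd1, with a peak at 3.37 in replicate 1 only. A single replicated peak of 79212 bp on chromosome 11, from 96268363 to 96347574, spanned the promoters from Hoxb9 to Hoxb3. The highest signal value of each cluster lay in paralogs 2 to 9. Hoxa4 had 34.2 in replicate 1 and 40.4 in replicate 2, Hoxa2 34.3 and 31.3, Hoxd3 and Hoxd4, whose annotated starts share a peak, 34.4 and 34.6, Hoxb6, Hoxb7 and Hoxb8 38.9 and 38.0 at the long peak, Hoxb9 38.9 and 28.7 there, Hoxb3, Hoxb4 and Hoxb5 38.9 and 25.8 there, and Hoxd8 28.1 and 37.5. Hoxa7 had 29.97 and 30.3, Hoxa3 20.5 and 30.3, Hoxb2 27.1 and 25.3, Hoxa5 and Hoxa6 23.4 and 23.0, Hoxa1 25.1 and 20.3, Hoxc9 17.3 and 23.3, Hoxc8 20.6 and 18.8, Hoxc6 14.6 and 12.9 and Hoxa9 11.3 and 14.2. The annotated start of Hoxa3 lies between those of Hoxa6 and Hoxa7, and its replicated peak is the one that marks Hoxa7. The marked genes of paralogs 10 to 13 had values of at most 12.7, but such values were also found elsewhere, with 7.68 and 10.4 for Hoxc4, 8.04 and 8.71 for Hoxd9 and 5.04 and 5.76 for Hoxb1. In the pooled list, however, Hoxc4 had a higher signal value, 29.65. Hoxa10 had 9.34 and 12.7, Hoxc10, and Hoxc5 through the same peak at its annotated start, 6.87 and 8.69, Hoxd10 5.84 and 7.67, Hoxa11 4.67 and 6.91 and Hoxc11 3.89 and 3.28. Hoxa13, Hoxb13, Hoxc12 and Hoxd13 had no promoter peak in either replicate, Hoxc13 and Hoxd12 had one in replicate 2 only (3.84 and 4.23), and Hoxd11 had one in each replicate (2.41 and 3.79) but none in the replicated list. In the list of replicate 2 alone, 8 of the 12 posterior genes were marked, and the difference was 29.6 percentage points (Fisher's exact p = 0.0246).

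**Figure D3:**
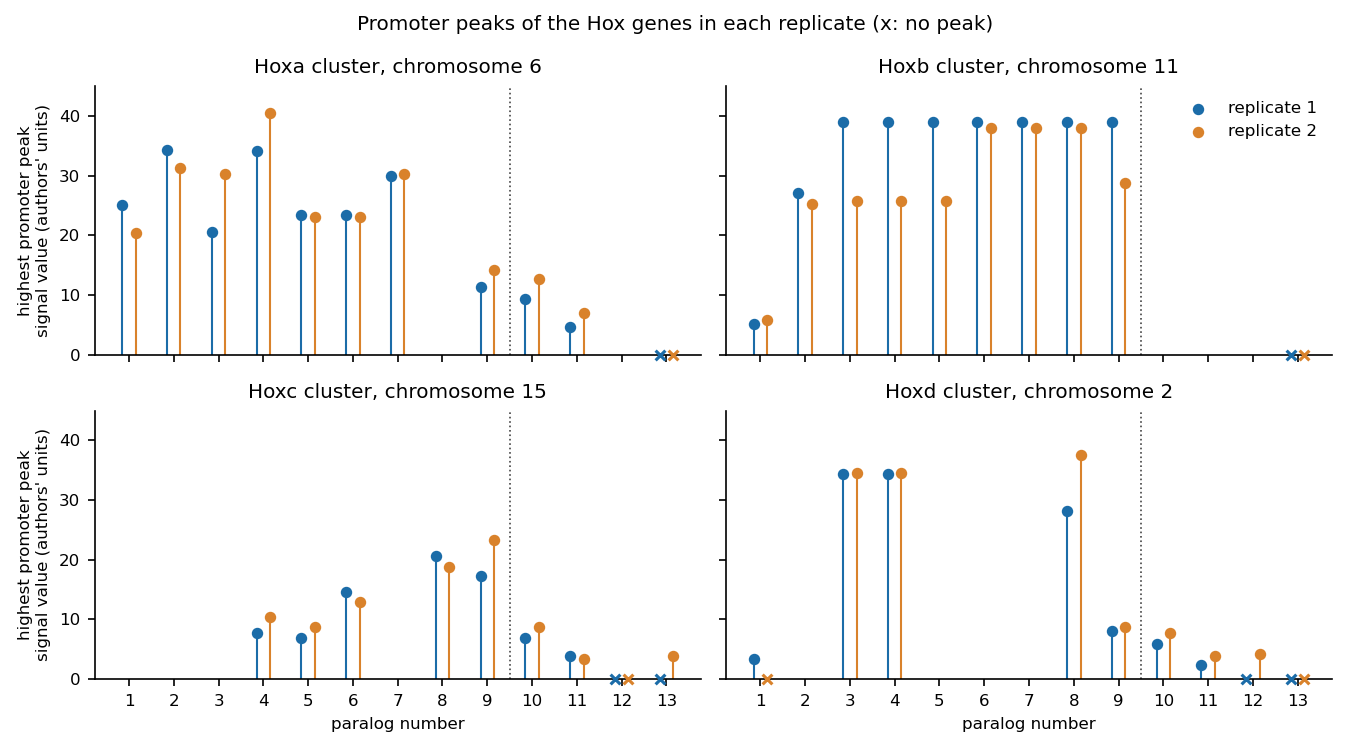
Highest signal value of a promoter peak (vertical axis, the authors' units) of each Hox gene by paralog number in the 4 clusters, in replicate 1 and replicate 2; crosses mark genes without a peak. Hoxa10 to Hoxa11, Hoxc10 to Hoxc11 and Hoxd10 to Hoxd11 lie between 2.41 and 12.7, and Hoxa13, Hoxb13, Hoxc12 and Hoxd13 have no peak in either replicate. Values are those at annotated starts, and that of Hoxa3 lies between the starts of Hoxa6 and Hoxa7.

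Stitched into domains, the replicated peaks formed 15652 regions, of which the 25 with the longest acetylated sequence held 1.07 Mb, or 4.72% of all bases in replicated peaks. All 4 Hox clusters were among the first 5. The HoxC domain had the most bases in replicated peaks, 123.9 kb in 56 peaks. It lay on chromosome 15 between 102951319 and 103182089, from Hoxc11 past Hoxc4 to Smug1. Its span of 230.8 kb was shorter than that of the next domain, 325.7 kb. More of its bases in peaks lay past the annotated start of Hoxc4 than before it, in peaks joined by the stitching. The peaks up to that start covered fewer bases than the domains of Gse1, HoxB and HoxA given below. The first rank of HoxC thus depends on the peaks past it. HoxB followed in the third place with 94.7 kb, HoxA with 83.0 kb and HoxD with 55.0 kb. The second domain, 108.6 kb in 98 peaks on chromosome 8, lay in the body of Gse1, with Gins2 as the nearest TSS.

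The other domains that held a protein-coding TSS were those of Cstad with 49.9 kb in replicated peaks, the transcription factor co-repressor gene Ncor2 with 39.1 kb, Bahcc1 with 34.6 kb, the zinc finger genes Zic1 and Zic4 with 31.5 kb, Cxxc5 with 30.3 kb, 14 histone genes of the Hist1 cluster such as Hist1h4h with 27.7 kb, Zmynd8 with 27.2 kb, Cuedc1 with 26.9 kb, Urm1 and Cercam with 26.9 kb, the Notch receptor gene Notch1 with 26.4 kb, Skida1 and Mllt10 with 26.1 kb, Igdcc3 and Parp16 with 25.7 kb, the retinoic acid receptor gene Rara (with Gjd3) with 25.3 kb, Midn and Cirbp with 24.3 kb, Cpa1, Cep41 and Mest with 23.8 kb, and the tubulin genes Tuba1a and Tuba1b with 23.7 kb. A domain of 26.4 kb lay nearest to Cdk5rap3. A group of 3 domains held no protein-coding TSS but a gene of the neural microRNA miR-9 each: Mir9-3 with 44.2 kb on chromosome 7, nearest to Polg, Mir9-1 with 36.7 kb on chromosome 3, nearest to Rhbg, and Mir9-2 with 27.7 kb on chromosome 13, 211243 bp from Mef2c. The lists of the single replicates gave 24843 and 25898 domains, over 1.5 times as many. In each case 21 of the 25 domains overlapped 1 of the top 25 of the single-replicate list by bases in peaks.

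**Figure D4:**
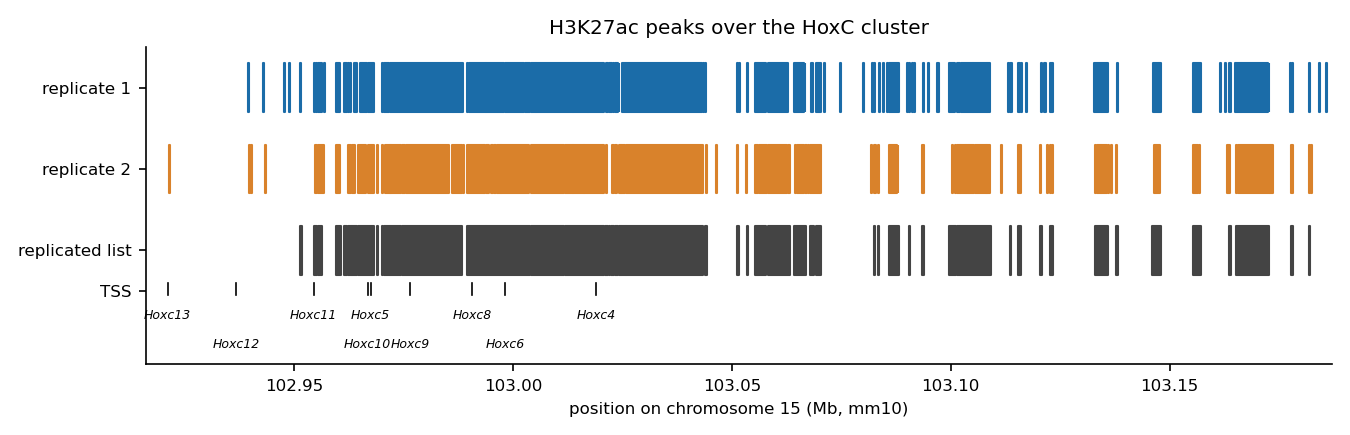
Map of the peaks of replicate 1 (102 peaks), replicate 2 (96) and the replicated list (56) over the HoxC domain on chromosome 15, with position in Mb on mm10 and the annotated TSS of each Hoxc gene. Replicated peaks begin next to Hoxc11 and extend past Hoxc4; Hoxc12 and Hoxc13 lie outside them.

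Distal peaks were then searched for binding motifs of transcription factors of the neural tube. SOX motifs, bound by the Sox factors of progenitors, were found in 58.4% of distal peaks against 46.4% of GC-matched windows, and the CAGCTG E-box, bound by basic helix-loop-helix factors, in 36.4% against 27.1%. Homeodomain motifs were found in 10.3% against 7.30%, and the octamer of POU factors in 3.16% against 2.17%. Adjusted exact p-values were 7.29e-95, 4.81e-66, 7.83e-20 and 5.54e-07 by Fisher's exact test over 15087 pairs. RFX, TEAD, MEF2 and ETS sites, the CAGATG E-box and direct repeats bound by retinoic acid receptors were also higher, by 1.04 to 2.00 times with adjusted exact p from 0.00851 to 0.0480, which makes 10 of 20 motifs higher and 0 lower against windows matched on GC alone. GLI, GATA, TCF/LEF, HNF4, HNF1, NFI, CTCF, REST, AP-1 and YY1 motifs did not pass the test against these windows. The windows held more repeat sequence than the peaks, 29.6% against 11.8%. With windows matched on repeats as well, homeodomain motifs (1.27 times), the octamer (1.52 times), SOX (1.19 times) and the CAGCTG E-box (1.24 times) stayed higher, as did ETS (3.08 times, adjusted exact p = 0.00155, against 1.95 times before), and AP-1 was lower (0.797 times, adjusted exact p = 2.21e-09). The calls for the CAGATG E-box, RFX, TEAD, MEF2 and the retinoic acid receptor repeat ended there, with adjusted exact p from 0.769 to 0.954, which leaves 5 motifs higher and 1 lower. The flanks of the same peaks differ from them in composition, with 45.55% GC against 49.99% and 24.8% repeats against 11.7%. Against these flanks homeodomain motifs (0.869 times, adjusted exact p = 0.000379) and GATA (0.845 times, adjusted exact p = 9.39e-05) were lower. The octamer was not called (1.18 times, adjusted exact p = 0.0775). SOX (1.16 times) and the CAGCTG E-box (1.72 times) were higher, as were the CAGATG E-box (1.10 times, adjusted exact p = 2.21e-08) and ETS (2.29 times, adjusted exact p = 0.0376). How much of this comes from composition was not tested. Over whole peaks GLI (0.649 times, adjusted exact p = 0.0066) and CTCF (0.702 times, adjusted exact p = 0.0469) were lower and TCF/LEF was higher (1.26 times, adjusted exact p = 0.0353). The weaker motifs depended on the background or on the replicate: from the peaks of replicate 2 alone the retinoic acid receptor repeat was not called (1.16 times, adjusted exact p = 0.404) and 1 motif, GLI, was lower (0.763 times, adjusted exact p = 0.0131), and from those of replicate 1 alone ETS was not called (1.5 times, adjusted exact p = 0.0774). TCF/LEF was higher in both, 1.28 times in replicate 2 and 1.16 times in replicate 1 (adjusted exact p = 0.000511 and 0.0438).

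The X chromosome carried few replicated peaks. It held 492, or 3.01 per Mb of sequenced bases, which is 23.9% of the autosomal density of 12.6 per Mb (95% interval 21.8 to 26.1%). In the lists of the single replicates the figure was 18.7% each. Of the 948 protein-coding genes on X 23.0% had a replicated promoter peak, against 43.4% of the 20807 on autosomes. Of the X peaks, 50.2% lay at promoters, and of the autosomal peaks 31.2%. The Y chromosome held 1 replicated peak, at a promoter.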

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

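Replicated peaks on unplaced scaffolds were outside all comparisons, and 4 of them were present, above the limit that a count of 0 would set. The first, on scaffold GL456216 assigned to chromosome 4 (positions 15601 to 17374, 1774 bp), had a signal value of 34.9 in the replicated list, with 28.15 in replicate 1 and 29.35 in replicate 2; only 0.258% of the replicated peaks on the chromosomes were higher. Scaffold JH584304 held a peak of 223 bp with a signal value of 1.86 and another of 406 bp with 2.07. The peak of 223 bp overlapped a peak of replicate 1, with a signal value of 2.15, but none of replicate 2. Scaffold GL456233, assigned to X, held a peak of 431 bp with a signal value of 3.91.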

How the results depend on the processing

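Of 483 alternative values for 68 results, 388 kept their direction and their side of the threshold (or stayed within their error), 40 fell short of the threshold, 36 changed direction, 13 newly passed it and 6 moved. The overlap settings with q of at most 5%, the top 20000 peaks and stricter peaks against a whole list, the lists with q of at most 5%, the windows matched on repeats and the motif values of single replicates were chosen after seeing the data. Promoter calls for neural progenitor, pan-neuronal, anterior and central Hox, housekeeping, forebrain, heart, surface ectoderm, liver and pluripotency genes, distal calls for progenitor, pan-neuronal, neurogenic, dorsoventral and central Hox genes, and the SOX and CAGCTG motifs kept direction and call in all alternatives run, with adjusted exact p up to 0.0290 for promoters. Shared peaks ranged from 30.7% to 91.5%, above shifted positions in each case, and the Hox contrast from 29.6 to 63.0 percentage points. Most reversals were in lists close to the background that passed no test. Where calls ended under stricter peaks or other backgrounds, the cause was not tested, as for all changes given here. The unknown depth limits what the weak peaks can show, and with 2 replicates each value without 1 of them is that of a single list. For the replicate overlap and the replicate contrast no value without a replicate exists, and the 2 alternatives of the contrast say nothing of stability, since its test could not pass.

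With single-replicate lists in place of the replicated one (without replicate 1 or without replicate 2), the ranges were: intron share 42.9% to 43.2%; promoters of posterior Hox 50% to 66.7%, mature glia 20% to 33.3%, somite 44.0% to 56.0% and blood 20% to 30.0%; distal ratios of forebrain 0.296 to 0.425, neural crest 2.05 to 2.40, mature glia 1.01 to 1.07, somite 1.62 to 1.97 and heart 0.897 to 1.34; lists with fewer distal peaks 0 to 1; domains 24843 to 25898; retinoic acid receptor repeats 1.16 to 1.42, ETS 1.5 to 1.63 and motifs lower 0 to 1; X density 18.7% to 18.7%.

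By -log10 p, rho was 0.720 instead of 0.698. With the stricter peak threshold the share kept in the replicated list was 98.8%, the intron share 28.2%, promoters of dorsoventral genes 26.7%, neurogenic 50%, neural crest 35.0% and endothelium 5.56%, and distal ratios were 3.57 for anterior and 3.58 for posterior Hox, 0.0 for forebrain, 1.53 for midbrain and 2.86 for neural crest, with 5 lists higher and 0 lower instead of 8 and 1. With the pooled list, introns held 40.4%, promoter shares were 50% for posterior Hox, 26.7% for mature glia and 48.0% for somite genes, and the heart distal ratio was 0.963. With a promoter window of 500 bp, introns held 38.6% and promoter shares were 40% for dorsoventral, 41.7% for posterior Hox, 30.0% for neural crest and 13.3% for mature glia genes. With 2.5 kb, introns held 33.8%, and mature glia had 20%, somite 44.0% and endothelium 44.4%. With every transcript start, introns held 30.9% and exons 2.75%, and dorsoventral genes had 43.3%, posterior Hox 50%, mature glia 20% and endothelium 50%.

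With a background matched on promoter GC the members' own shares stay as they are and the comparison changes: dorsoventral 43.3% against 64.1%, neurogenic 67.5% against 58.4%, midbrain 21.4% against 56.2%, mature glia 13.3% against 33.6% and blood 5.0% against 23.0%. With distal windows of 20 kb, the ratios were 0.194 for forebrain, 1.53 for midbrain, 3.23 for neural crest and 3.95 for somite genes, with 0 lists lower. With 100 kb they were 0.486 for forebrain, 1.33 for mature glia, 0.749 for blood and 2.34 for endothelium, with 0 lists lower. With random lists matched on promoter peaks they were 0.109 for forebrain, 1.21 for midbrain, 1.09 for mature glia and 2.42 for somite genes, with 0 lists lower, and with peaks of q of at most 5% 1.02 for midbrain.

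With whole peaks the CAGATG E-box had a ratio of 1.025 and ETS 1.59, with 2 motifs lower. With windows matched on GC and repeats the CAGATG E-box had 0.998, RFX 1.03, retinoic acid receptor repeats 1.08, TEAD 1.01 and MEF2 1.11, with 5 motifs higher instead of 10 and 1 lower. Against flanks the homeodomain motif had 0.869, the POU octamer 1.18, RFX 1.11, retinoic acid receptor repeats 1.35, TEAD 0.998 and MEF2 0.826, with 4 motifs higher and 2 lower.

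For the results that lost or gained a call, the adjusted exact p for promoters ranged over the alternatives from 0.000232 to 0.248 for neurogenic, 0.0197 to 1.0 for dorsoventral, 0.000492 to 0.284 for blood, 0.0226 to 0.556 for mature glia, 0.00961 to 1.0 for endothelial and 0.00553 to 0.385 for midbrain genes. The adjusted permutation p for distal peaks ranged from 0.00179 to 0.382 for forebrain, 0.00878 to 0.0865 for neural crest, 0.0116 to 0.187 for somite, 0.000285 to 0.0865 for anterior Hox and 0.000152 to 0.0865 for posterior Hox genes. For motifs the adjusted exact p ranged from 1.46e-33 to 0.000379 for the homeodomain, 1.81e-08 to 0.0775 for the octamer, 0.00155 to 0.120 for ETS and 0.0438 to 0.933 for retinoic acid receptor repeats.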

Other observations

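The gene families and microRNA genes in the first 2 paragraphs were chosen after the data had been seen, as were the tests of the forebrain pattern, of peak strength and of the dorsoventral genes further on; the test of background positions and the tests on X were set before their results were seen.

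Of 25 gene families grouped by symbol, 6 had promoter peaks more often and 6 less often than other genes. Neighbouring genes of a family can share peaks, as Zic1 and Zic4 do at their promoters. The tests of families count genes as independent and do not allow for this, so their p-values can be too small. Background genes were not matched on promoter GC content for the families. Such matching ended the promoter call of the neurogenic list above, so the family calls could depend on it too. Notch receptors and ligands had a replicated promoter peak in 8 of 9 cases (adjusted exact p = 0.0176 by Fisher's test over the 25 families) and 5.87 times as many distal peaks within 50 kb as random lists. Ephrins, ligands of axon guidance, had one in 7 of 8 cases (adjusted exact p = 0.0299) with 4.84 times as many distal peaks, Sox genes in 14 of 19 cases (adjusted exact p = 0.0240) with 3.91 times as many, and Frizzled receptors of Wnt signalling in 8 of 10 cases (adjusted exact p = 0.0455). The 5 Zic genes had 8.33 times as many distal peaks as random lists, and 4 of them a promoter peak (adjusted exact p = 0.265). Histone genes of the clusters were marked in 58 of 67 cases (adjusted exact p = 3.14e-13) and Zfp zinc finger genes in 234 of 391 cases (adjusted exact p = 7.59e-12), the latter with fewer distal peaks than random lists (0.656 times). The families with fewer promoter peaks were these: of 57 protocadherin genes of the clusters 1 was marked, of 32 GABA and glutamate receptor genes 7, of 106 keratin genes 1, of 327 vomeronasal receptor genes 1, of 1093 olfactory receptor genes 0 and of 64 defensin genes 0, with adjusted exact p from 4.22e-268 to 0.0453. Other families of signalling and axon guidance were not called at promoters: Wnt ligands with 4 of 19 (adjusted exact p = 0.111) and Fgf ligands with 7 of 22 (adjusted exact p = 0.445), both below other genes, Eph receptors with 10 of 14 (adjusted exact p = 0.0562), semaphorins with 11 of 20 (adjusted exact p = 0.314), plexins with 6 of 9 (adjusted exact p = 0.265) and Slit and Robo genes with 4 of 7 (adjusted exact p = 0.505). Pou genes (9 of 15), kinesins (23 of 38), retinoid receptors (3 of 6), and Irx (4 of 6), Lhx and Lmx (2 of 10) and Hes and Hey genes (5 of 9) were not called either. Distal peaks were higher round Pou genes (3.41 times) and semaphorins (2.71 times). The protein-coding genes with the most distal peaks within 50 kb were Mrpl23 with 25, Vapb with 21, Ncor2 with 20 and Notch1 with 19. Outside the Hox clusters, the widest promoter peaks belonged to Tnrc18 (11944 bp), Msi1 (11250 bp), Zic1 and Zic4 (11044 bp), and the Hox cofactor genes Meis2 (10399 bp) and Meis1 (10208 bp).

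Of 1174 microRNA genes, the 6 with the most acetylated sequence within 50 kb lay in the Hox clusters: Mir10a with 88.6 kb in replicated peaks, Mir615 with 83.2 kb, Mir196a-2 with 60.4 kb, Mir196b with 57.1 kb, Mir10b with 55.0 kb and Mir196a-1 with 53.2 kb. Mir9-3 had 44.99 kb, Mir9-1 37.8 kb and Mir9-2 27.7 kb, a mean of 36.8 kb for these 3 genes against 2.92 kb for the others. Mir3093, beside Mir9-1, had 37.8 kb, and Mir7687 with 37.4 kb and Mir3089 with 30.8 kb also came before Mir9-2. MicroRNA genes of the nervous system were spread over the ranking. Mir219a-2, of the oligodendrocyte microRNA miR-219, had 28.8 kb but Mir219a-1 6.70 kb, Mir137 had 1.79 kb, and the neuronal Mir124a-1, Mir124a-2 and Mir124a-3 had 16.7, 13.9 and 10.5 kb. The muscle microRNA gene Mir206 and the liver microRNA gene Mir122 had 0 kb, as did 28.6% of the genes other than those of miR-9. Mir451a, of red blood cells, had 4.58 kb, above the mean of the others, and the muscle genes Mir133a-1 and Mir1a-2 had 1.10 kb each. A permutation test of the miR-9 genes was run and dropped as void, since these genes had been picked for their values.

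About 60% of each replicate's peaks had no counterpart that covered at least 50% of their length in the other replicate; with an overlap of 1 bp, 48.7% of the peaks of replicate 1 and 49.5% of those of replicate 2 had one. Unshared peaks lay at promoters in 8.75% of cases in replicate 1 and 8.43% in replicate 2, 5.15 and 4.95 times the share of shifted positions. This does not decide whether they are background positions without acetylation. Some unshared peaks partly overlap peaks of the other replicate, and the shifts take background to be even along each chromosome. Background as the source of all or a part of the unshared peaks stays open. Shared peaks lay at promoters in 36.1% and 35.3% of cases. Only 36.5% and 32.1% of the unshared peaks were found in the pooled list, against 99.8% of the shared peaks in each replicate. Peaks close to the authors' threshold remain a candidate explanation, since the share with a counterpart was at least 98.5% in the strongest of 10 classes and at most 15.9% in the weakest, though it did not rise at each step among the weaker classes. The depth of the libraries is unknown and was not tested as a cause, and with 1 group no biological explanation was tested.

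None of the 22 forebrain genes had a replicated promoter peak. Promoter GC content does not account for this, since 43.3% of other genes of the same GC content had one (stratified exact p = 8.13e-07). A need for a peak in both replicates, which the sources do not state as the rule of the replicated list, does not either. Only 4.55% of the list, Emx2 alone, had a peak in at least 1 replicate, against 51.0% of other genes (Fisher's exact p = 4.00e-06). Nor do alternative promoters, since 0% had a replicated peak at any annotated transcript start against 45.8% of other genes (adjusted exact p = 1.10e-05). How far forebrain tissue was left out of the dissected sample stays open, and no biological explanation was tested.

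The X chromosome carried 23.9% of the autosomal peak density. X held 5.80 protein-coding genes per Mb against 8.68 on autosomes. At the rate of genes of the same GC content on autosomes and X together, 30.6% of its genes would have a promoter peak. The observed share was 23.0% (stratified exact p = 3.64e-10). Fewer genes and lower promoter GC content thus do not account for all of the low density. Nor does repeat sequence, 46.8% of X against 33.5% of autosomes, since the density outside repeats was still 29.9% of the autosomal one. Weaker enrichment at X promoters, as from 1 active copy per cell, remains a candidate explanation, with a median pooled signal value of 5.72 at 218 marked X promoters against 7.43 at autosomal ones (two-sided permutation p = 0.00014). The promoters in this comparison were not matched on GC content, so the part of GC content in the difference stays open. Male and female embryos were pooled, and the number of active copies was not tested.

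A further hypothesis was that dorsoventral genes, which are active in only part of the tissue, may have weaker promoter peaks and so fewer calls. Their 11 promoters with values in both replicates had a median signal value of 7.29, below the 16.1 of 23 neural progenitor promoters (two-sided permutation p = 0.0303). The housekeeping promoters were added once this had been seen. The median of 22 of them was 7.71, and the difference from it was not past the threshold (two-sided permutation p = 0.931). The values do not decide the hypothesis. Only 13 of the 30 dorsoventral genes had a replicated promoter peak, so the promoters too weak for a call are left out of the comparison.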
